A study of Macaca nemestrina with 58 samples.

How the data were processed

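Gene expression was measured in vaginal biopsies of 15 pig-tailed macaques (Macaca nemestrina) on 58 Affymetrix arrays designed for the rhesus macaque, so probes read the transcripts of a related species. The animals were 9 given DMPA and 6 given LNG, with untreated baseline biopsies of every animal: 13 animals had 2 and 2 had 1. Groups, doses and cycle phases were taken from the sample labels. The labels give the doses no unit, and the label (A-) on 5 of the 12 treated LNG arrays is not explained in the sources used here.

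The deposited values are on a log2 scale, between 1.37 and 14.57, with 1 column per array. The distributions of the arrays are alike, with medians between 6.07 and 6.25, as after a normalization between arrays; affy and Partek are named as the authors' tools, without versions. The method of background correction, normalization and summarization is not given in the sources used here. The values were used as deposited.

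Of 52865 probe sets, 158 controls were left out, and of the other 52707 those under the 40th percentile of the mean over samples (log2 mean of 5.53) were removed, which left 31624. Of all probe sets, 24969 carry 1 gene symbol, 361 carry several and 27535 carry none. The kept probe sets name 11199 genes, each represented by its probe set with the highest mean. Of these genes 4774 have over 1 kept probe set. Positions on a genome are not used here. An array labelled as a duplicate was averaged with its partner, which gave 57 samples. The log2 values of the duplicate and its partner differed with an SD of 0.486 (r = 0.961). Other pairs of arrays from the same animal had a median SD of 0.685 and a lowest SD of 0.358.

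Linear models were fitted in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, with the animal as a fixed block and moderated variances, and p values were adjusted by the Benjamini-Hochberg method. Adjusted p values are from limma unless another test is named, and a probe set passed at an adjusted p under 0.05. Since each animal belongs to 1 arm, the DMPA and LNG changes share no control samples. The treated times, DMPA 1D4 and 2D2 and LNG 5th and 7th, were each compared with the pooled baseline, with the other time of the same arm and, for 2D2 and 5th, with the luteal and follicular phases and between the arms. The labelled DMPA dose was a linear term at 2D2, the LNG High and Low animals were compared at the 5th time, and the 4 cycle phases were compared in the baseline. The 2 luteal and the 2 follicular phases were averaged with equal weights. Errors of log2 changes are standard errors of the fit.

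Gene lists were written before the data were examined: 29 lists with 698 genes, of which 434 genes had a kept probe set and 5 to 32 genes per list were measured. They cover squamous epithelium (cornified envelope, epithelial proteases and inhibitors, suprabasal squamous, basal keratinocyte, cell junctions), columnar epithelium, defence (antimicrobial, interferon response and restriction factors, cytokines and chemokines), HIV receptors and homing, hormone response (estrogen-responsive, progestin- and glucocorticoid-responsive, steroid receptors and metabolism), glycogen metabolism, proliferation, immediate early and stress, stroma (extracellular matrix, fibroblast, smooth muscle, endothelium) and immune and other cells (T cell, natural killer and cytotoxic, B and plasma cell, macrophage and dendritic, Langerhans cell, neutrophil, mast cell, blood, melanocyte and nerve). Some genes are on several lists, and 2 older symbols were replaced by current ones. Lists were tested with camera, with a preset correlation of 0.01 and with the correlation estimated, and with fry; p values were adjusted over the 29 lists of a comparison. The p values of fry vary slightly with the order of the model's columns, which was held fixed.

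Genes to be named were set by a rule written before the data were examined. For the comparisons of DMPA 2D2 and LNG 5th with the baseline and of the luteal with the follicular phases, these were the 8 largest rises and 8 largest falls that passed, with the same direction in all animals but 1 at most where changes per animal exist. For other comparisons they were the 5 largest of each direction. Where fewer than 3 genes passed, the 3 with the smallest p were named. To these were added up to 4 members of each list with the smallest p, and PGR, ESR1, CD4, CXCR4, ITGA4, ITGB7, CD207, DSG1, IVL, FKBP5 and MKI67. 1 other gene of this set is not reported here.

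RNA quality was read from the 3' minus 5' difference of the GAPDH and actin control probe sets. The GAPDH difference was 2.14 in the duplicate array and 1.71 in its partner, so it can vary between arrays of the same animal and phase. The stroma score of a sample is the mean of the fibroblast and smooth muscle genes. Changes of these 3 measures from the animal's own baseline were tested by exact two-sided permutation within animals and adjusted over 12 tests. The 54 genes of the cornified envelope, protease and suprabasal lists are called squamous genes, and their mean per sample was taken on the log2 scale.

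The recovery of known changes was tested on simulated data. Each change was the same in all samples of a group, in randomly drawn probe sets, with noise drawn independently per probe set. The shares therefore do not hold for genes whose change varied among animals. At DMPA 2D2, 58.2%, 88.1% and 97.0% of genes with a simulated log2 change of 0.5, 1 and 2 were recovered, and at LNG 5th 35.8%, 85.1% and 95.5%. Between the LNG High and Low animals the shares were 1.49%, 32.8% and 75.8%.

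Alternatives chosen before the data were examined were no filter or a filter at the 60th percentile, no block or a random block for the animal, centring on the array median, quantile normalization, trended and robust variances, array weights, leaving out each animal in turn, leaving out the duplicate array, 1 probe set per gene, other probe sets or their mean, leaving out the (A-) arrays, the baseline phases as separate groups, subsets of arrays, and late luteal against early follicular. Added after the data were seen were the GAPDH difference, the actin difference and the stroma score as covariates, leaving out the array with the largest GAPDH difference, leaving out each animal in turn for the tests of the lists and, for the squamous genes by DMPA dose, the baseline sample with their lowest mean. Other splits of the samples were drawn 100 times with a fixed seed, or all counted where fewer exist. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.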

Results

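Vaginal pinch biopsies of 15 pig-tailed macaques were profiled on 58 rhesus macaque expression arrays. Of the animals, 9 were given DMPA (depot medroxyprogesterone acetate, an injectable progestin) and 6 were given LNG, the labels' name for the arm on a combined oral contraceptive (a progestin with an estrogen). Each animal first had untreated baseline biopsies in a named phase of the menstrual cycle. These make 28 baseline samples: 10 early follicular, 5 late follicular, 4 early luteal and 9 late luteal. A late follicular sample is the mean of 2 arrays of the same animal and phase. After DMPA there were 8 samples at the time labelled 1D4 and 9 at the time labelled 2D2, at doses labelled 0.5, 1.5 and 2.5. After LNG there were 6 samples at the time labelled 5th and 6 at the time labelled 7th, with 3 animals labelled High and 3 labelled Low. The medians of the arrays lay between 6.07 and 6.25 on the log2 scale, and the number of arrays limits the precision. The control transcript GAPDH, compared at its 3' and 5' ends as a measure of RNA quality, had a 3' minus 5' difference of 1.66 ± 0.31 (SD, n = 28) on the log2 scale at baseline.

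The first comparison asks how the vaginal mucosa after DMPA differed from the animal's own baseline. No animal was left untreated at the later times, so drug, time and repeated biopsy cannot be told apart in either arm. At 2D2, genes of the mature squamous epithelium fell far below baseline. TMPRSS11B, a serine protease of squamous epithelia, fell by 7.31 ± 1.13 (SE, n = 9 animals) on the log2 scale, or 158-fold. CRNN, which makes the late differentiation protein cornulin, fell by 6.40 ± 0.97, and the protease inhibitor gene SPINK7 fell by 6.23 ± 1.16. Each of these genes was lower in 8 of 9 animals. The largest rise was that of MYBPC1, a myosin-binding protein gene, at 4.52 ± 0.74 or 23.0-fold, in 9 of 9 animals. In all, 8874 of 31624 probe sets passed in limma, 5055 higher and 3819 lower, or 3811 and 4758 with the arrays centred on their median, and 1106 of them changed at least 2-fold, 338 higher and 768 lower. Counted over the brightest probe set of each named gene, 1921 genes rose and 1579 fell of 11199.

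Among the genes with the largest rises at 2D2, VNN2, of the vanin family of pantetheinases, rose by 3.86 ± 0.75 (SE) on the log2 scale and PCDH8, a protocadherin gene, by 3.05 ± 0.71. ATP6V0A4, a proton pump subunit gene, rose by 2.84 ± 0.45 and the urea transporter gene SLC14A1 by 2.83 ± 0.45. DMBT1, a scavenger receptor gene of mucosal surfaces, rose by 2.61 ± 0.54 in 8 of 9 animals. The peptide transporter gene SLC15A2 and PRR15L rose by 2.58 ± 0.50 and 2.51 ± 0.45. Among the largest falls were LOC717850 with a log2 change of -6.20 ± 1.09, LORICRIN, the main protein of the cornified envelope, with -5.96 ± 1.26, and LOC714943 with -5.64 ± 0.96. SPINK6 had a log2 change of -5.40 ± 1.08 and the kallikrein protease gene KLK12 one of -5.25 ± 0.80. These genes fell in 8 of 9 animals each.

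**Figure D1:**
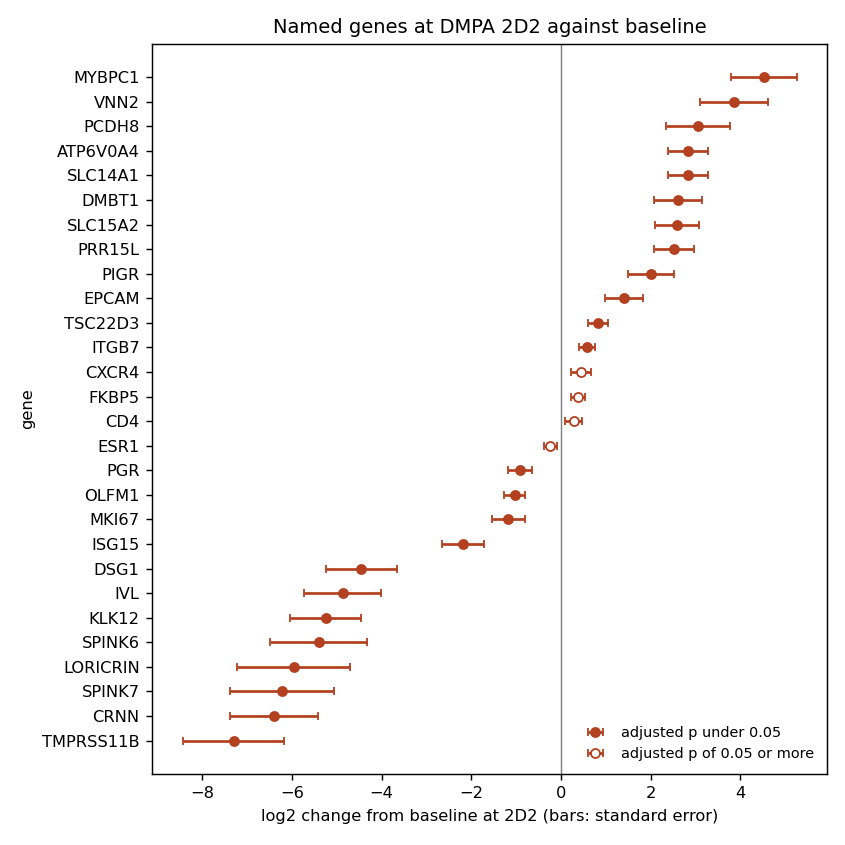
Log2 change of named genes at DMPA 2D2 against baseline (x axis, log2 units; n = 9 animals) with the standard error as bars; filled points passed at an adjusted p under 0.05 and open points did not. TMPRSS11B lies lowest at -7.31 and MYBPC1 highest at 4.52.

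Gene groups of the epithelium fell together at 2D2. Of 24 measured genes of the cornified envelope, the protein shell of fully mature squamous cells, 23 fell over all genes tested and 24 fell adjusted over the list alone, with a median of -3.73. Examples are IVL, encoding involucrin, with -4.87 ± 0.86 (SE), the cross-linking enzyme gene TGM3 with -3.65 ± 0.60, and DSG1, the adhesion gene of upper-layer desmosomes, with -4.45 ± 0.79. Of 16 epithelial proteases and inhibitors, 12 fell both over all genes and adjusted over the list alone, with a median of -2.55. The kallikrein gene KLK8 fell by 2.53 ± 0.43, while another probe set of it had 0.84. Of 14 suprabasal squamous genes 11 fell on either count, with a median of -1.39, among them RHCG with -3.27 ± 0.57 and the keratin gene KRT16 with -2.38 ± 0.47, while another probe set of each had 0.81 and 0.25. Camera called these lists lower with adjusted p of 2.08e-19, 2.16e-10 and 3.69e-07. None held with an estimated correlation, where the cornified envelope had adjusted p = 0.205, the proteases adjusted p = 0.246 and the suprabasal genes adjusted p = 0.354. The list means were lower in 8 of 9 animals for each of the 3 lists. The other animal was PPi2 (DMPA_0.5_2D2 replicate 1), whose baseline includes late luteal replicate 4, the baseline sample with the lowest squamous mean. Over the 54 genes of these lists its mean changed by 0.48, and by -1.12 without that baseline sample. Of 26 cell junction genes, 9 fell and 3 rose, or 9 and 4 adjusted over the list alone: the connexin gene GJB6 fell by 3.21 ± 0.57 and the plakophilin gene PKP1 by 1.94 ± 0.46, while the tight junction gene TJP3 rose by 0.84 ± 0.17. Camera did not call that list, with an adjusted p of 0.0689. Of 24 proliferation genes, 14 fell over all genes and 16 adjusted over the list alone, with a median of -0.65, a camera adjusted p of 1.22e-06 and an adjusted p = 0.627 with an estimated correlation. The division marker MKI67 fell by 1.17 ± 0.37, CCNB1 by 1.36 ± 0.35 and FOXM1 by 1.20 ± 0.29.

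Defence genes of the epithelium also moved at 2D2. Of 16 antimicrobial genes, 9 fell and 3 rose, or 10 and 3 adjusted over the list alone, with a median of -0.83; S100A12 fell by 3.04 ± 0.48 (SE), WFDC12 by 2.90 ± 0.49, the elafin gene PI3 by 2.31 ± 0.44 and the defensin gene DEFB1 by 2.03 ± 0.38. Camera called the list with an adjusted p of 0.00211, against adjusted p = 0.289 with an estimated correlation. Of 28 interferon response and restriction factor genes, 13 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -0.63, a camera adjusted p of 3.50e-04 and an adjusted p = 0.674 with an estimated correlation. ISG15, a ubiquitin-like interferon product, fell by 2.19 ± 0.48, IFI27 by 0.92 ± 0.23 and IRF7 by 0.83 ± 0.23, each in 9 of 9 animals, and SLFN11 rose by 0.88 ± 0.21. Of 32 cytokines and chemokines, 9 fell and 0 rose on either count, with a camera adjusted p of 0.0128 and an adjusted p = 0.664 with an estimated correlation. The falls were led by epithelial members of the interleukin 1 family: IL36RN with -5.03 ± 0.99, IL36A with -4.12 ± 0.70 and the receptor antagonist gene IL1RN with -3.02 ± 0.51.

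Some hormone-related and HIV-related genes also changed at 2D2. PGR, encoding the progesterone receptor, fell by 0.92 ± 0.28 (SE) in 7 of 9 animals, while ESR1, encoding estrogen receptor alpha, had a log2 change of -0.24 ± 0.15 that did not pass. Of 21 estrogen-responsive genes, 7 fell and 0 rose, or 8 and 0 adjusted over the list alone, with a median of -0.38, a camera adjusted p of 0.00235 and an adjusted p = 0.0807 with an estimated correlation; OLFM1 fell by 1.04 ± 0.24, TFF3 by 0.39 ± 0.11 and CA12 by 0.42 ± 0.13. Of 12 genes of steroid receptors and metabolism, 3 fell on either count: PGR, the retinoic acid hydroxylase gene CYP26B1 with -0.78 ± 0.25, and HSD17B8 with -0.47 ± 0.14. Of 25 progestin- and glucocorticoid-responsive genes, 2 rose and 3 fell, or 2 and 2 adjusted over the list alone. TSC22D3, a glucocorticoid-induced gene, rose by 0.82 ± 0.23 and MAOA by 0.67 ± 0.21, NFKBIA fell by 0.39 ± 0.12 and GADD45B by 0.47 ± 0.15, and FKBP5 had 0.38 ± 0.16 with an adjusted p of 0.0624. Of 13 HIV receptor and homing genes, 3 rose and 1 fell, or 3 and 2 adjusted over the list alone: the integrin genes ITGB7, ITGAE and ITGB1 rose by 0.57 ± 0.18, 0.35 ± 0.11 and 0.58 ± 0.21, and the lectin gene CLEC7A fell by 1.05 ± 0.29. CD4 had 0.28 ± 0.18 and CXCR4 had 0.44 ± 0.23, and neither passed. ITGA4 was not analysed here, and CD207 lay under the brightness filter.

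Markers of other cell types at 2D2 mostly did not pass. Of 6 basal keratinocyte genes 3 rose on either count, ITGB4 by 0.45 ± 0.13 (SE; another probe set had -0.16), CAV1 by 0.30 ± 0.11 and ITGA6 by 0.25 ± 0.10. Of 12 columnar epithelium genes 5 rose and 1 fell, among them the immunoglobulin receptor gene PIGR with a rise of 2.00 ± 0.51, KRT18 with 1.12 ± 0.30 and FOXJ1 with 0.74 ± 0.23; the list mean was higher in 9 of 9 animals by 0.53 ± 0.36 (SD). In the Langerhans cell list 2 of 7 rose, EPCAM by 1.41 ± 0.41 and FCGBP by 1.69 ± 0.57; both are also made by columnar epithelium, and the list mean was higher in 9 of 9 animals by 0.51 ± 0.40 (SD). In the lists of fibroblasts (13 genes), smooth muscle (10), endothelium (15), natural killer and cytotoxic cells (11) and B and plasma cells (11), 0 genes passed over all genes or adjusted over the list alone. In the extracellular matrix list 1 of 25 rose, TNC by 1.21 ± 0.30. The T cell list had 1 rise among 17, UBASH3A at 0.42 ± 0.16, and the mast cell list 1 among 5, KIT at 1.02 ± 0.38; adjusted over the list alone both had 0. Macrophage and dendritic genes (22) had 1 rise, TYROBP by 0.91 ± 0.29, and 1 fall, CLEC10A by 0.20 ± 0.07. The neutrophil list (5 genes) had the fall of S100A12, the blood list (6) the fall of GP9 by 0.21 ± 0.06, and the melanocyte and nerve list (5) the rise of NCAM1 by 0.19 ± 0.06. Of 11 glycogen metabolism genes 3 rose, PPP1R3D by 0.59 ± 0.15, GAA by 0.38 ± 0.11 and PHKB by 0.40 ± 0.12. Of 15 immediate early and stress genes 2 rose, DDIT4 by 0.62 ± 0.16 and CA9 by 0.41 ± 0.14, and GADD45B fell. For extracellular matrix, fibroblast, endothelium, natural killer and blood genes, the median, the mean or the direction of the set tests differed in sign.

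The squamous falls at 2D2 came with a shift in RNA quality. The stroma score had no mean shift that could be told from its wide spread among animals. The GAPDH 3' minus 5' difference was 2.43 ± 0.70 (SD) at 2D2, higher than the animal's own baseline in 8 of 9 animals by a mean of 0.74, with an exact two-sided permutation p of 3.05e-04 and 0.00366 after adjustment over 12 such tests. The actin difference was higher in 7 of 9 animals by a mean of 0.23, with an adjusted exact p of 0.0229. The stroma score, the mean of the fibroblast and smooth muscle genes, was higher in 3 of 9 animals. Its mean change was 0.11 ± 1.71 (SD), with an exact permutation p of 0.832. With the GAPDH difference as a covariate 0 probe sets passed, and with the actin difference 1469 did. Without animal BB981 (DMPA_1.5_2D2 replicate 1) the count was 5523.

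**Figure D2:**
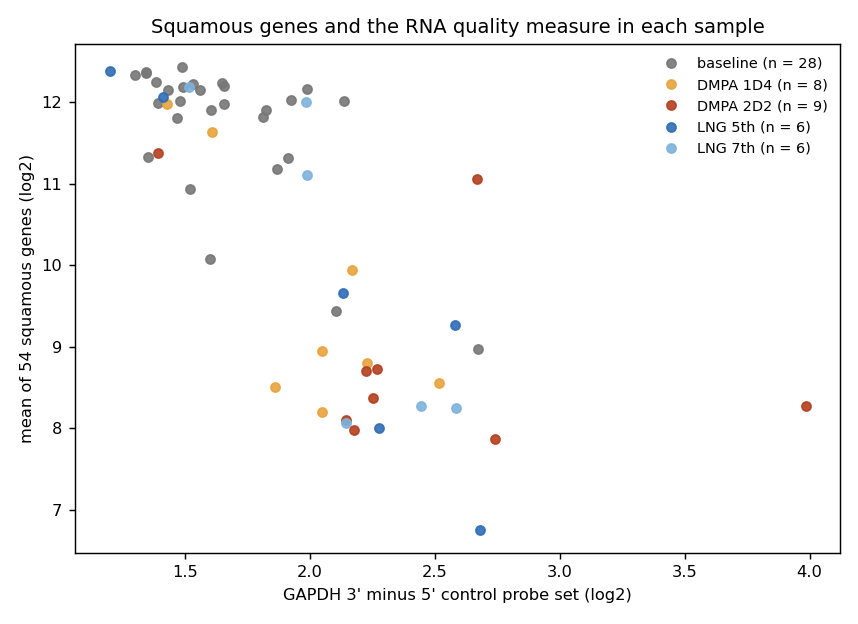
Mean log2 level of 54 squamous genes (the cornified envelope, protease and suprabasal lists; y axis) against the GAPDH 3' minus 5' difference (x axis, log2) in each of 57 samples, colored by group. Of the 28 baseline samples 2 lie under a mean of 10, against 6 of 8 at DMPA 1D4, 7 of 9 at DMPA 2D2, 4 of 6 at LNG 5th and 3 of 6 at LNG 7th.

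At the earlier DMPA time, 1D4, squamous genes were also lower. MYBPC1 rose by 3.87 ± 0.78 (SE, n = 8 animals), VNN2 by 3.73 ± 0.79, MSMB, a secreted mucosal protein gene, by 3.53 ± 0.87, PCDH8 by 2.87 ± 0.75 and DMBT1 by 2.84 ± 0.57. SPINK6 fell by 5.57 ± 1.14, TMPRSS11B by 5.56 ± 1.19, and CRNN by 5.13 ± 1.03. SPINK7 fell by 5.02 ± 1.22 and LOC717850 fell by 4.91 ± 1.15. Of the cornified envelope genes 23 of 24 fell on either count, of the proteases and inhibitors 11 of 16 on either count, of the suprabasal genes 8 of 14, or 10 adjusted over the list alone, and of the proliferation genes 16 of 24, or 21 adjusted over the list alone. Markers of deeper tissue were higher at 1D4: 5 of 25 extracellular matrix genes rose and 1 fell, or 6 and 1 adjusted over the list alone, and 3 of 10 smooth muscle genes rose, or 9 adjusted over the list alone. Camera called these 6 lists with adjusted p of 0.00734 or less, and each had adjusted p = 0.619 with an estimated correlation. Without animal PPi2 the smooth muscle median moved from 1.63 to 1.30 and its camera adjusted p to 0.0580. The mean of the columnar epithelium genes was higher in 8 of 8 animals by 0.53 ± 0.28 (SD) and that of the Langerhans cell genes in 7 of 8 by 0.63 ± 0.46, with 3 of 12 genes rising and 1 falling and 2 of 7 rising; camera called neither, with adjusted p of 0.217 and 0.251. The stroma score was higher in 6 of 8 animals by a mean of 1.10, with an adjusted exact permutation p of 0.0416, and the GAPDH difference in 6 of 8 by 0.31, with an adjusted exact p of 0.0919. Over all probe sets 3559 were higher and 3775 lower, 7334 in all, or 2607 and 5004 with the arrays centred on their median. The count was 3091 without animal PHQ1, 3093 without BB0499, 3314 without BB981 and 4164 without BB0540, 1631 with the GAPDH covariate and 490 with the stroma score as a covariate.

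Set directly against each other, 2D2 and 1D4 did not differ at any probe set: limma called 0, with 1655 at an unadjusted p under 0.05. The genes with the smallest p, which did not pass, were SPIRE2, FOS and CPXM2, with log2 differences of 0.62 ± 0.14 (SE), 1.86 ± 0.42 and -2.30 ± 0.54. Extracellular matrix genes had a median difference of -1.09 and endothelial genes one of -0.58, with camera adjusted p of 3.57e-11 and 1.66e-08; with an estimated correlation these were adjusted p = 0.248 and adjusted p = 0.280. The endothelial median was -0.32 without animal PHQ1. A change of 1 on the log2 scale, the same in every animal, was recovered for 83.6% of simulated genes in this design. This share does not cover genes whose change varied among animals.

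Among the 9 animals at 2D2, 0 probe sets followed the labelled dose in limma, with 1304 at an unadjusted p under 0.05. The genes nearest to passing were PI3, with a slope of -1.79 ± 0.43 (SE) log2 units per unit of labelled dose, LILRAB with 0.99 ± 0.27 and RGS2 with 0.99 ± 0.28. The cornified envelope list had a median slope of -1.22 and the proliferation list one of -0.40, with camera adjusted p of 3.73e-09 and 2.83e-08. With an estimated correlation both had adjusted p = 0.482. Without animal PPi2 the cornified envelope slope was -0.77, and without BB770 the proliferation slope was -0.24. The labels give the doses no unit.

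The LNG comparison asks the same of the oral contraceptive. At the 5th time no gene passed over all genes in limma, and the squamous lists lay lower than baseline with the tissue beneath the epithelium higher. In limma 0 probe sets were called, and the lowest adjusted p was 0.0544. At an unadjusted p under 0.05 there were 6828, against 1581 expected on average by chance. Another split of the same samples gave 3529 called probe sets, so this excess alone does not show an effect. Under other settings some passed: 198 with 1 probe set per gene, 748 with the filter at the 60th percentile, 755 with a random block for the animal, 1708 with array weights and 1808 with the baseline phases as separate groups. The genes with the smallest p, none passing, were MINK1, a kinase gene, with -0.62 ± 0.12 (SE, n = 6 animals), ARHGAP27 with -0.78 ± 0.16 and SERPINE2, a protease inhibitor gene, with 1.85 ± 0.38. A change of 1 on the log2 scale, the same in every animal, was recovered for 85.1% of simulated genes in this design. The median SE was 0.15 over all probe sets and 0.58 over the 54 squamous genes, so this share does not hold for those genes.

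Adjusted over the list alone, 20 of 24 cornified envelope genes fell at the 5th time, with a list median of -2.53, as did 15 of 16 proteases and inhibitors (median -2.11) and 14 of 14 suprabasal genes (median -1.42); over all genes each had 0. Values include TGM1 with -3.32 ± 0.85 (SE), CNFN with -2.92 ± 0.73, SCEL with -2.25 ± 0.53, KLK10 with -2.08 ± 0.50, TMPRSS11D with -2.29 ± 0.55 and GRHL1 with -1.97 ± 0.51. Adjusted over the list alone, 18 of 26 cell junction genes fell, with a median of -0.96; CLDN4 had -1.03 ± 0.29. In the same way 7 of 16 antimicrobial genes fell, among them PGLYRP3 with -1.66 ± 0.39 and S100A8 with -1.28 ± 0.33, and 5 of 32 cytokines and chemokines fell, among them IL1RN with -2.89 ± 0.63 and IL36A with -3.67 ± 0.87. Of the tissue beneath, 13 of 25 extracellular matrix genes rose and 1 fell adjusted over the list alone, with a median of 1.23, along with 11 of 13 fibroblast genes (median 1.67), 9 of 10 smooth muscle genes (median 2.28), 2 of 15 endothelial genes and 3 of 5 mast cell genes. COL12A1 had 1.85 ± 0.45, COL3A1 had 1.74 ± 0.54, DCN had 1.56 ± 0.49, ASPN had 2.46 ± 0.75, ACTG2 had 3.38 ± 1.04, LMOD1 had 2.44 ± 0.72, CLDN5 had 0.79 ± 0.26 and the mast cell gene KIT had 1.49 ± 0.47. Camera called the squamous, junction, antimicrobial, matrix, fibroblast, smooth muscle and mast cell lists with adjusted p of 0.00608 or less, and each of these had adjusted p = 0.215 with an estimated correlation. It also called endothelium at 8.50e-06 (adjusted p = 0.304 with an estimated correlation), cytokines at 0.0108 (adjusted p = 0.442), T cells lower at 0.0108 (adjusted p = 0.548) and proliferation lower at 1.64e-04 (adjusted p = 0.547).

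The other lists at the 5th time had few members past the test adjusted over the list alone and 0 over all genes. The steroid receptor, basal keratinocyte and HIV receptor lists had 1 rise and 1 fall each, the estrogen-responsive list 2 falls, the melanocyte and nerve list 2 rises, the glycogen and immediate early lists 1 rise each, and the neutrophil list 1 fall. The interferon, proliferation, progestin-responsive, columnar, T cell, natural killer, B cell, macrophage, Langerhans and blood lists had 0. The genes fixed in advance did not pass either: PGR had 0.02 ± 0.34 (SE), ESR1 -0.15 ± 0.19, CD4 -0.09 ± 0.23, CXCR4 0.07 ± 0.29, ITGB7 -0.19 ± 0.22, DSG1 -2.72 ± 0.97, IVL -2.90 ± 1.06, FKBP5 -0.08 ± 0.19 and MKI67 -1.08 ± 0.46.

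The stroma score was higher at the 5th time in 5 of 6 animals by a mean of 1.87, with an adjusted exact permutation p of 0.0296, and the GAPDH difference was higher in 5 of 6 by a mean of 0.40, with an adjusted exact p of 0.0705. In animal BB4800 (LNG_Low_5th replicate 3) the 54 squamous genes changed by a mean of -5.21, and without that animal their median moved from -2.02 to -1.31. Without it the medians also moved from -1.42 to -0.79 for the suprabasal, -0.96 to -0.27 for the cell junction, -0.71 to -0.30 for the antimicrobial, -0.39 to -0.20 for the cytokine, -0.56 to -0.27 for the proliferation and -0.29 to -0.11 for the T cell list, which camera then no longer called (adjusted p of 0.114), while the fibroblast median was 1.68. Without animal BB173 the cytokine median was -0.25 and camera did not call it (adjusted p of 0.118). The count of probe sets was 3186 without animal BB4870, whose array carries the label (A-), 920 without BB269 and 717 without PPi2, a DMPA animal that enters only through the pooled variance.

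**Figure D3:**
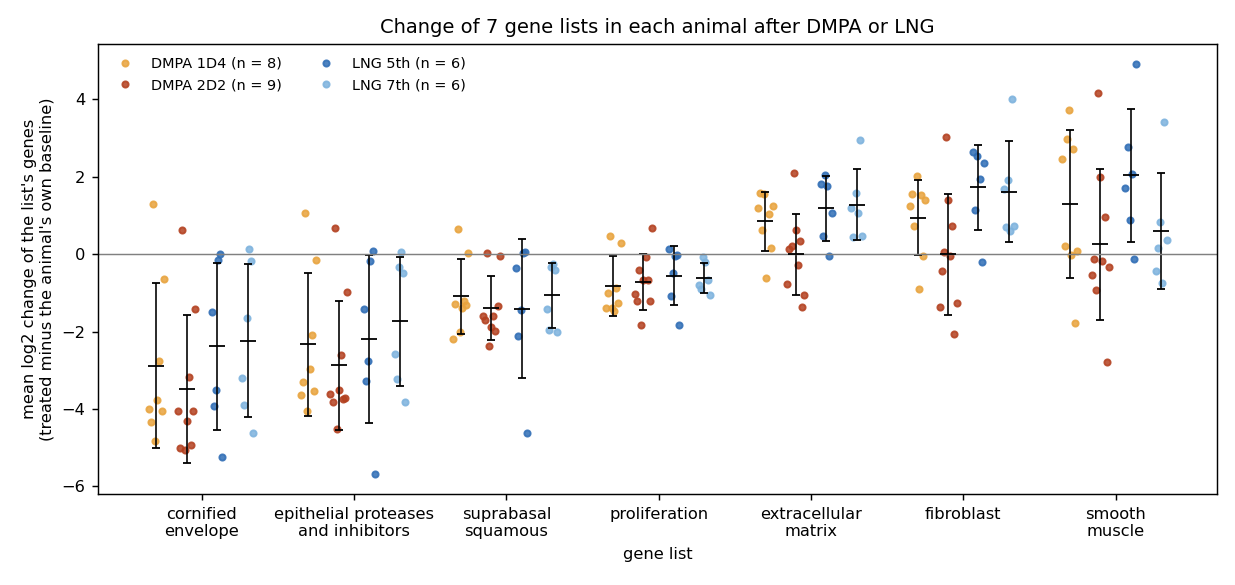
Mean log2 change of the genes of 7 lists (x axis) from the animal's own baseline (y axis, log2 units); each point is an animal, and the bars give the mean and SD of the 8, 9, 6 and 6 animals at DMPA 1D4, DMPA 2D2, LNG 5th and LNG 7th. The cornified envelope list had means of -2.88, -3.49, -2.38 and -2.24 in that order, and 1 animal in each group lay above 0.

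At the 7th time 2 probe sets were called, both lower and neither with a gene name, with 7487 at an unadjusted p under 0.05. The named genes with the smallest p, none passing, were KDM3A, a histone demethylase gene, with -0.73 ± 0.15 (SE, n = 6 animals), the glycolysis gene ALDOC with -1.5 ± 0.31 and MINK1 with -0.58 ± 0.12. Adjusted over the list alone, 19 of 24 cornified envelope genes, 8 of 16 proteases and inhibitors and 11 of 14 suprabasal genes fell, and 20 of 25 extracellular matrix (1 fell), 9 of 13 fibroblast, 12 of 15 endothelial and 4 of 5 mast cell genes rose; over all genes each had 0. Camera called these lists with adjusted p of 0.0152 or less, and none held, with adjusted p = 0.510 or more with an estimated correlation. It also called proliferation genes lower at 3.60e-05 and macrophage and dendritic genes higher at 0.0131, with adjusted p = 0.534 and adjusted p = 0.572 with an estimated correlation. Without animal BB4870 the macrophage and dendritic median moved from 0.45 to 0.13 and the mast cell median from 0.74 to 0.42, with camera adjusted p of 0.253 and 0.0817; the macrophage and dendritic median was 0.33 without BB537, with a camera adjusted p of 0.0988, and 0.83 without BB269. The GAPDH difference was higher in 6 of 6 animals by a mean of 0.47 (adjusted exact permutation p of 0.0123), the actin difference in 5 of 6 by 0.17 (0.0247) and the stroma score in 6 of 6 by 1.17 (0.100). Under other settings the count was 560 with the filter at the 60th percentile, 532 with a random block, 3572 with array weights and 1950 with the baseline phases as separate groups. The count became 1094 without animal BB269 and 811 without PPi2, and 0 or 4 without each other animal.

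The 7th and 5th times did not differ at any probe set in limma, with 946 at an unadjusted p under 0.05. DOCK8, STOML1 and PAPSS1 had the smallest p without passing, with log2 differences of 0.77 ± 0.18 (SE, n = 6 animals), -0.55 ± 0.14 and -0.32 ± 0.09. T cell genes had a median difference of 0.44 and smooth muscle genes one of -1.26, with camera adjusted p of 2.11e-09 and 9.30e-08; with an estimated correlation these were adjusted p = 0.247 and adjusted p = 0.394. Without animal BB4800 these medians were 0.17 and -0.54, with camera adjusted p of 8.99e-04 and 0.0943, and the smooth muscle median was -2.32 without BB4870.

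The High and Low LNG animals at the 5th time were compared with each other, 3 against 3. The squamous lists lay higher in the High animals: adjusted over the list alone, 14 of 24 cornified envelope genes (median 3.34), 11 of 16 proteases and inhibitors (2.71), 14 of 14 suprabasal genes (2.57), 17 of 26 junction genes (1.44), 15 of 28 interferon genes (1.26) and 10 of 24 proliferation genes (1.07) passed. Over all genes 0 passed in limma, with 4690 at an unadjusted p under 0.05 and a lowest adjusted p of 0.108. Camera called these 6 lists with adjusted p of 9.32e-07 or less, and none held, with adjusted p = 0.282 or more with an estimated correlation. RNA quality differed along with the doses: the GAPDH 3' minus 5' difference was 2.28, 2.58 and 2.68 in the Low arrays and 2.13, 1.41 and 1.20 in the High arrays, so the groups did not overlap, as 10% of the splits of 3 against 3 would give by chance. The genes nearest to passing were PIP with -0.85 ± 0.18 (SE), LOC694628 with 2.96 ± 0.64 and PLXNA4 with -1.30 ± 0.29. The count became 466 without animal BB173 and 381 without BB537, which leaves 2 Low animals. With all animals it was 397 with a random block for the animal, 467 with no block and 769 with array weights. Without animal BB4800, also Low, the junction median was 0.45 and the suprabasal median 1.70.

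The cycle phases were compared among the baseline samples, in a fit that also holds the treated samples. In the luteal phases MASP1, a complement protease gene, was higher than in the follicular phases by 3.36 ± 0.76 (SE) on the log2 scale, and CTHRC1, of collagen matrix turnover, by 2.95 ± 0.63. SPHKAP rose by 2.78 ± 0.64, the matrix gene THBS2 by 2.67 ± 0.73, STMN2 by 2.65 ± 0.63, GALNT15 by 2.60 ± 0.68, CRISPLD2 by 2.49 ± 0.63 and PROM1 by 2.27 ± 0.56 (another probe set had -0.18). HSD17B2, which inactivates estradiol, fell by 2.19 ± 0.55, the melanocyte gene OCA2 by 1.80 ± 0.30, the keratin gene KRT10 by 1.27 ± 0.31 (another probe set had 0.024), TENM1 by 1.10 ± 0.30 and LOC712049 by 1.08 ± 0.28. In limma 303 probe sets were higher and 239 lower, 542 in all, or 323 and 500 with the arrays centred on their median. With the baseline arrays alone 960 passed.

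By group, 1 of 25 extracellular matrix genes was higher in the luteal phases, or 6 adjusted over the list alone, with a median of 0.58; MMP2 rose by 2.26 ± 0.52 (SE). Of 22 macrophage and dendritic genes 0 passed over all genes and 7 rose adjusted over the list alone, with a median of 0.53, among them C1QA with 1.13 ± 0.32 (another probe set had -0.11). Of 13 HIV receptor and homing genes 1 rose, ITGB1 by 0.66 ± 0.17, or 3 adjusted over the list alone. Of 25 progestin- and glucocorticoid-responsive genes ZBTB16 rose by 1.28 ± 0.34 and HSD17B2 fell, or 2 rose and 1 fell adjusted over the list alone. Camera called these 4 lists with adjusted p of 0.0446 or less, each with adjusted p = 0.749 or more with an estimated correlation. It also called fibroblast, endothelial and T cell genes higher and proliferation genes lower, with adjusted p of 0.0469 or less, against adjusted p = 0.986 with an estimated correlation for each. The camera calls of the progestin-responsive, endothelial, T cell and proliferation lists each ended without any 1 of several animals, with adjusted p of up to 0.129 (without BB981), 0.176 (without BB269), 0.563 (without BB405) and 0.181 (without BB4800). In these lists DPT rose by 2.22 ± 0.58, CD8B by 0.60 ± 0.15, and FLT4 fell by 0.29 ± 0.07; adjusted over the list alone the counts were the same, with 0 among the proliferation genes. Of the cornified envelope list KRT10 alone passed, and of the proteases, junction and suprabasal lists 0 did. PGR had 0.42 ± 0.28, CD4 had 0.39 ± 0.18 and MKI67 had -0.41 ± 0.34, none passing. The luteal count rests on few animals: it was 6 or less without BB4800, BB537, BB173, BB967 or PPi2 in turn, 17 without BB981, 49 without BB269, 230 without PHQ1, 842 without BB770 and 1420 without BB4870. It was 7 with the GAPDH difference, 16 with the stroma score and 219 with the actin difference as a covariate. Under other settings it was 13 with no block for the animal, 1317 with a random block, 3321 with array weights and 4110 as late luteal minus early follicular.

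A test for any difference among the 4 phases called 1405 probe sets, or 243 with the baseline arrays alone. OCA2 led it, with mean log2 levels of 7.28 ± 0.86 (SD, n = 10) in the early follicular, 7.77 ± 0.53 (n = 5) in the late follicular, 6.0 ± 1.25 (n = 4) in the early luteal and 5.55 ± 0.98 (n = 9) in the late luteal phase, at an adjusted p of 0.0123 in limma. PIAS2, CYP7B1, an oxysterol hydroxylase gene, TMEM44 and MOXD1 followed. APOE, an apolipoprotein gene, had 9.91 ± 1.43, 9.81 ± 0.27, 11.13 ± 0.51 and 11.77 ± 0.88 in the same order. The count was 2 without animal PPi2, 8 without BB967, 37 without BB269, 723 without BB537, 748 without BB173, 764 without BB770, 788 without BB981 and 2232 without BB4870, 1 with the GAPDH covariate, and 2 with the stroma score as a covariate. With no block for the animal it was 0, and with array weights 5233.

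DMPA 2D2 and LNG 5th were also set against the 2 parts of the cycle; the counts against luteal and follicular phases were not tested against each other. DMPA 2D2 differed from the luteal phases at 3357 probe sets, 1765 higher and 1592 lower, and from the follicular phases at 12712, 6779 higher and 5933 lower. With the arrays centred on their median the higher and lower counts were 1449 and 1737 against the luteal and 5255 and 7538 against the follicular phases. TMPRSS11B fell by 8.07 ± 1.28 (SE, n = 9 animals) against the luteal and by 7.27 ± 1.26 against the follicular phases, CRNN by 7.09 ± 1.09 and 6.35 ± 1.08, and MYBPC1 rose by 5.05 ± 0.81 and 5.14 ± 0.80. Of 24 cornified envelope genes, 22 fell against the luteal phases (23 adjusted over the list alone) and 24 against the follicular phases, with camera adjusted p of 4.38e-26 and 4.87e-14; with an estimated correlation these were adjusted p = 0.0609 and adjusted p = 0.585. Of 22 macrophage and dendritic genes 11 rose and 1 fell against the follicular phases, or 12 and 1 adjusted over the list alone, and 0 passed against the luteal phases, with camera adjusted p of 0.0680 and 0.929. The luteal count was 1738 without animal BB0540, 1885 without BB405, 2062 without BB981 and 2074 without BB521. With the GAPDH covariate the luteal count was 1 and the follicular count 0, and with the actin covariate the luteal count was 968 and the follicular count 7153.

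LNG at the 5th time differed from the follicular phases at 6004 probe sets, 2983 higher and 3021 lower (2707 and 3576 with the arrays centred on their median), and from the luteal phases at 0 in limma, with 3870 at an unadjusted p under 0.05. Against the follicular phases MASP1 rose by 4.12 ± 0.95 (SE, n = 6 animals), CTHRC1 by 4.03 ± 0.80, the smooth muscle myosin gene MYH11 by 3.82 ± 1.11, OGN by 3.60 ± 1.00 and LOC710096 by 3.59 ± 1.10. TMPRSS11B fell by 4.86 ± 1.42, LOC717850 by 4.60 ± 1.33, SPINK7 by 4.35 ± 1.46, IL36RN by 4.27 ± 1.19 and CRNN by 4.19 ± 1.22. Of 24 cornified envelope genes 18 fell, and of 25 extracellular matrix, 13 fibroblast and 10 smooth muscle genes 16, 10 and 9 rose; adjusted over the list alone the counts were 24, 20, 12 and 9. Camera called these lists with adjusted p of 4.43e-06 or less, and each had adjusted p = 0.361 with an estimated correlation. Against the luteal phases FOXE1 had -1.73 ± 0.37, SERPINE2 had 1.81 ± 0.40 and IL1RN had -3.06 ± 0.67, the smallest p without passing. The follicular count was 0 without animal BB4800, 3177 without BB537, 3741 without BB967 and 3832 without BB173, 0 with the GAPDH covariate and 0 with the stroma score as a covariate, and the luteal count was 200 without BB4870. Against the follicular phases the median of the 54 squamous genes was -2.16 (median SE of 0.59). It was -1.61 (0.69) with the stroma score and -1.10 (0.49) with the GAPDH difference as a covariate.

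The final comparison asks whether DMPA and LNG differed in their change from baseline, tested as the difference of the changes between the arms. No probe set passed in limma, with 2688 at an unadjusted p under 0.05 and a lowest adjusted p of 0.506. Estrogen-responsive genes were lower after DMPA than after LNG by a median of -0.22 over 21 genes, with a camera adjusted p of 9.93e-04 that held with an estimated correlation at adjusted p = 0.0452; 0 of the 21 passed singly, and fry gave an adjusted p of 0.126. The median was -0.13 without animal BB0540 and -0.14 without BB269. Extracellular matrix, fibroblast and smooth muscle genes had medians of -1.21, -1.86 and -1.90, with camera adjusted p of 2.13e-07 or less; with an estimated correlation these were adjusted p = 0.273, adjusted p = 0.273 and adjusted p = 0.280. Cell junction and T cell genes had medians of 0.48 and 0.47, with camera adjusted p of 7.80e-04 and 0.00117, against adjusted p = 0.576 and adjusted p = 0.509 with an estimated correlation. Without animal BB4800 these medians were -0.05 and 0.34, with camera adjusted p of 0.374 and 0.0426. The cornified envelope list had a median of -0.96 with a camera adjusted p of 7.67e-05, and adjusted p = 0.576 with an estimated correlation; the median was -0.63 without animal BB269 and -0.57, with a camera adjusted p of 0.0632, without BB4870. The genes with the smallest p, none passing, were CNTN1 with -1.59 ± 0.34 (SE), FAM167B with -0.68 ± 0.16 and NUCB2 with -0.64 ± 0.16. A difference of 1 on the log2 scale, the same in every DMPA animal, was recovered for 76.1% of simulated genes in this design. Genes whose change varied among animals are not covered by this share.

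The changes of both arms were also compared across genes. Over 11199 genes, which are not independent replicates, the log2 changes at DMPA 2D2 and LNG 5th had a Pearson r of 0.725 and a Spearman rho of 0.645. Of the 3500 genes called at DMPA 2D2, 3158 (90.2%) had an LNG change of the same sign, and over these genes the slope of the LNG change on the DMPA change was 0.638. With the LNG samples relabelled within animals, 8 of 100 splits, the real one included, gave an r as high, with a median of 0.139 and a highest of 0.823 among the others, and 9 gave a share as high, with a median of 55.9% and a highest of 95.3%. With LNG at the 7th time r was 0.757 and the share with the same sign 91.0%. The arms share no animals, and r lay between 0.623 without animal BB0499 and 0.776 without BB269. The GAPDH difference also rose in both arms, by a mean of 0.74 at DMPA 2D2 and 0.40 at LNG 5th. Whether a shared shift in RNA quality gave this likeness of the changes was not tested.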

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

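The tests with the GAPDH, actin and stroma covariates, the single (A-) array and the doses apart were chosen only after the data were seen. The fits with separate phases and without an animal were set before the data were examined, and were taken up as tests of an explanation only after the result was seen; the tests with the GAPDH slope of the baseline and the splits of the samples were set before their results were seen.

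The fall of the squamous genes at DMPA 2D2 came with a shift in RNA quality. Without a covariate the median of the 54 genes was -2.42 with a median SE of 0.47, and 46 of them passed. With the stroma score as a covariate the median was -2.36 with 46 passing. The mean change of that score was only 0.11 ± 1.71 (SD), so as a covariate it could move the median little and decides little. The score itself was higher in 3 of 9 animals, while the mean of the squamous genes fell in 8 of 9. That argues against more stroma, as this score measures it, as the main cause. With the actin covariate the median was -2.151 with 37 passing. That does not decide on RNA quality, since the interval of the actin slope, given below, reaches 71.0%. With the GAPDH covariate the median was -0.9926 with a median SE of 0.46 and 0 passed, so the calls ended because the change shrank, not because the error grew. The slope on GAPDH within baseline animals would give 57.07% of the mean fall, with a 95% interval from 21.1% to 93.1%, and it falls from -2.12 ± 0.61 (SE) to -1.26 ± 1.01 without the late luteal replicates 4 and 7. Within the DMPA arrays the slope on GAPDH was -0.81 ± 0.15, and the slope on actin within baseline animals would give 23.4% of the fall, with a 95% interval from -24.3% to 71.0%. So RNA quality and a change in the epithelium may both contribute and cannot be told apart here.

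At LNG 5th the squamous genes had a median of -2.02 with a median SE of 0.58. The actin difference rose by a mean of only 0.06, so as a covariate it could move the median little, and the median was -1.97. This test does not decide on RNA quality. With the GAPDH covariate the median was -1.09 with a median SE of 0.47, or 54.0% of its size. With the stroma score as a covariate the median was -1.302 with a median SE of 0.63, or 64.5% of its size, and without animal BB4800 it was -1.309 with a median SE of 0.59, or 64.8%. RNA quality as GAPDH measures it, more stroma in the biopsies and a single biopsy with little epithelium may each give part of the fall. They cannot be told apart from a smaller fall through the drug. Each remainder lies within the median SE of 50%, the bound set for the test. That SE is the median over single genes and does not measure the uncertainty of their median. An effect of the drug on the epithelium stays open, as untested.

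The absence of calls at LNG 5th, beside 6828 probe sets at an unadjusted p under 0.05 in limma, depended on how the animals were grouped. Without the (A-) array (LNG_High_5th(A-) replicate 1) 4117 probe sets passed, without LNG_High_5th replicate 2 234 did, and without any other array of that time 0 did. With the baseline phases as separate groups 1808 passed. For the Low animals alone against the baseline 5203 passed, and for the High animals 0 in limma, with 542 at an unadjusted p under 0.05; among the 20 choices of 3 of the 6 animals the highest other count was 3311, and all 8 choices with calls hold BB4800. At the 7th time 0 probe sets passed in limma for the same Low animals and 1 for the High animals. There 2603 and 5782 had an unadjusted p under 0.05. At the 5th time the GAPDH difference was 2.28 to 2.68 in the Low arrays and 1.20 to 2.13 in the High arrays. With it as a covariate 63 probe sets passed for the Low animals. The median of their squamous genes moved from -3.45 (median SE of 0.73) to -2.121 (median SE of 0.70), or 61.5% of its size. That lies within the median SE of single genes from the bound of 50%, so RNA quality and dose cannot be told apart here. A difference between doses, RNA quality, the unexplained label and the mix of phases are each a candidate explanation. The first 3 overlap, since the (A-) array belongs to a High animal and RNA quality follows the doses.

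Single animals lay far from the others by Dixon's test in 10 of 199 changes, where chance marks about 1 in 20 groups, or 9.95. Of these, 7 were at LNG 5th and 5 of the 7 were in animal BB4800 (LNG_Low_5th replicate 3). In that animal the changes were -1.58 for ITGB7 (others -0.27 to 0.39), -3.72 for the mean of the cell junction genes (others -0.70 to 0.02), -0.999 for basal keratinocyte genes (others -0.16 to 0.33), -1.36 for natural killer and cytotoxic genes (others -0.28 to 0.21) and 1.63 for melanocyte and nerve genes (others -0.21 to 0.31). The progestin- and glucocorticoid-responsive genes had -0.047 in LNG_High_5th replicate 2 (others 0.04 to 0.08), and the blood genes -0.79 in LNG_Low_5th replicate 2 (others 0.07 to 0.33). At DMPA 2D2, DMPA_0.5_2D2 replicate 1 (animal PPi2, whose baseline includes late luteal replicate 4, low in squamous genes) had a change of 0.22 for ATP6V0A4 (others 2.69 to 4.31) and of 4.15 for LORICRIN (others -9.83 to -4.78), and DMPA_0.5_2D2 replicate 3 had -0.825 for TSC22D3 (others 0.35 to 1.53). The change of the estrogen-responsive genes differed between the arms by a median of -0.22 (DMPA minus LNG), by a camera test of the difference itself with an adjusted p of 0.0452 with an estimated correlation; fry gave an adjusted p of 0.126, 0 of the 21 genes passed singly in limma, and the median was -0.13 without animal BB0540 and -0.14 without BB269.

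Other splits of the samples were counted for each comparison. The shares of splits are not adjusted over the comparisons. In some comparisons only the real labels among 100 splits gave a result as large, which makes chance unlikely. These were DMPA 2D2 against baseline (8874 real, 1371 highest other), luteal minus follicular (542, 158) and LNG 5th against follicular (6004, 3556). The same held with little margin for DMPA 2D2 against follicular (12712, 12313). Of 100 splits 2 were as large, the real one included, for DMPA 1D4 against baseline (7334 real, 8978 highest other), the 4 phases (1405, 3269) and DMPA 2D2 against luteal (3357, 7103). There another split gave more calls than the real labels, so chance is not excluded. In the last 2 a split gave more than double the real count, for a reason that was not examined. A low share of splits does not make the counts stable: without animal PPi2 luteal minus follicular had 6 and the phases had 2. Chance cannot be excluded for LNG 7th against baseline (10 splits, with 2 real and 3731 highest other). Why a split there gave many calls was likewise not examined. Nor can chance be excluded for the correlation of the arms' changes across genes (8 splits, with 0.725 real and 0.823 highest other). Where the real count was 0, every split is as large, so the count of splits says nothing about chance: LNG 5th against baseline (100 splits; 3529 highest other), LNG 5th against luteal (100; 6558), the difference between the arms (100; 2009), 2D2 against 1D4 (100; 3), the dose trend (100; 3) and LNG 7th against 5th (32 of 32; 1). In the first 3 of these the reason for the many calls of the highest other split was also not examined. For High against Low the 10 splits are too few, with 0 real and 0 for the highest other.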

How the results depend on the processing

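The covariates for GAPDH, actin and stroma, the array with the largest GAPDH difference left out and the animals left out of the tests of the lists were chosen only after the data were seen; the other alternatives were set before the data were examined. Over all alternatives, 338 counts stayed within 1.5 times their value and 124 moved; of the values of named genes 12824 kept direction and side of the threshold, 553 lost their call, 589 gained one, 113 changed sign without passing either way and 5 reversed. Where no reason is given, the cause was not tested.

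DMPA 2D2 against baseline, 8874 probe sets, lay between 5523 (without animal BB981) and 9960 (without BB770) when each animal was left out in turn. DMPA 1D4 lay between 3091 (without PHQ1) and 8614 (without PPi2), with 3093 without BB0499, 3314 without BB981 and 4164 without BB0540. LNG 5th against baseline lay between 0 and 3186 (without BB4870), with 920 without BB269, 717 without PPi2 and 1 without BB967. LNG 7th against baseline lay between 0 and 1094 (without BB269), with 811 without PPi2 and 4 without BB967 or BB981. The ranges were 0 to 0 for the difference between the arms, for LNG 7th against 5th and for the dose trend, 0 to 1 (without BB981) for 2D2 against 1D4, and 0 to 466 (without BB173) for High against Low, with 381 without BB537. The phase test lay between 2 (without PPi2) and 2232 (without BB4870), with 8 without BB967, 37 without BB269, 723 without BB537, 748 without BB173, 764 without BB770 and 788 without BB981. Luteal minus follicular lay between 2 (without BB4800) and 1420 (without BB4870), with 4 without BB537, 5 without BB173 or BB967, 6 without PPi2, 17 without BB981, 49 without BB269, 230 without PHQ1 and 842 without BB770. DMPA 2D2 against luteal lay between 1738 (without BB0540) and 4153 (without BB770), with 1885 without BB405, 2062 without BB981 and 2074 without BB521, and against follicular between 10645 (without PHQ1) and 13159 (without BB770). LNG 5th against luteal lay between 0 and 200 (without BB4870), and against follicular between 0 (without BB4800) and 7561 (without BB4870), with 3177 without BB537, 3741 without BB967 and 3832 without BB173. The correlation of the arms' changes lay between 0.623 and 0.776.

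With the GAPDH covariate the counts were 0 for DMPA 2D2 and LNG 7th against baseline, 1631 for DMPA 1D4, 1 for the phases, 7 for luteal minus follicular, 1 for DMPA 2D2 against luteal, and 0 for DMPA 2D2 and LNG 5th against follicular. Under it, MKI67 (0.089), CA12 (0.012) and KIT (-0.13) reversed at DMPA 2D2. With the actin covariate the counts were 1469 for DMPA 2D2, 0 for LNG 7th, 219 for luteal minus follicular, 968 for DMPA 2D2 against luteal and 7153 against follicular. With the stroma score as a covariate they were 490 for DMPA 1D4, 0 for LNG 7th, 2 for the phases, 16 for luteal minus follicular and 0 for LNG 5th against follicular, where the smooth muscle genes MYH11 (-0.26) and LOC710096 (-0.15) reversed; MYH11 is itself part of that score. Without the array with the largest GAPDH difference the counts were 1 for LNG 7th and 2220 for DMPA 2D2 against luteal.

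With no filter the counts were 1 for LNG 5th, 4 for LNG 7th and 1 for 2D2 against 1D4, and with the filter at the 60th percentile 748 for LNG 5th and 560 for LNG 7th. With 1 probe set per gene, where fewer features were tested, they were 3721 for DMPA 2D2, 198 for LNG 5th, 3095 for DMPA 1D4, 0 for LNG 7th, 729 for the phases, 303 for luteal minus follicular, 1559 and 5047 for DMPA 2D2 against luteal and follicular, and 2648 for LNG 5th against follicular.

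With no block for the animal the counts were 0 for LNG 7th, 39 for the difference between the arms, 2 for the dose trend, 467 for High against Low, 0 for the phases, 13 for luteal minus follicular, 1558 for DMPA 2D2 against luteal and 3864 for LNG 5th against follicular. With a random block they were 755 for LNG 5th, 532 for LNG 7th, 1 for the dose trend, 397 for High against Low and 1317 for luteal minus follicular. With array weights they were 1708 for LNG 5th, 11812 for DMPA 1D4, 3572 for LNG 7th, 1 for the difference between the arms, 5 for 2D2 against 1D4, 769 for High against Low, 5233 for the phases, 3321 for luteal minus follicular, 5337 for DMPA 2D2 against luteal and 1 for LNG 5th against luteal.

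With the phases as separate groups the counts were 1808 for LNG 5th and 1950 for LNG 7th, and without the (A-) arrays 2937 and 69. For LNG 7th the count was 0 with centring, with quantile normalization, without the duplicate array and with the LNG animals' arrays alone. Luteal minus follicular had 823 with centring, 832 with quantile normalization, 960 with the baseline arrays alone and 4110 as late luteal minus early follicular; the phases had 243 with the baseline arrays alone. With centring the larger share turned from higher to lower for DMPA 2D2 against baseline (3811 higher, 4758 lower), luteal minus follicular (323, 500) and DMPA 2D2 against luteal (1449, 1737) and follicular (5255, 7538), and the excess of lower ones grew for DMPA 1D4 (2607, 5004) and LNG 5th against follicular (2707, 3576). The arms' changes had r = 0.910 over genes called in either comparison, a set chosen for large changes.

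Another probe set reversed the sign for KLK8 (0.84), ITGB4 (-0.16), LAMA3 (-0.38), RHCG (0.81), KRT16 (0.25) and TPM2 (-0.44) at DMPA 2D2, and for PROM1 (-0.18) and KRT10 (0.024) in luteal minus follicular. Results of the lists with an estimated correlation are given with each comparison above. How many list calls held under the other alternatives was not counted. Probe sets under the filter, such as those of CD207, were tested only in the alternative with no filter, and the background of the arrays was not measured.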

Other observations

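The tests reported here, except the trend with the labelled dose, were chosen only after the squamous genes had been seen to differ among the DMPA animals.

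The fall of the squamous genes differed among the DMPA animals. At baseline the mean of the 54 genes was 11.70 ± 0.88 (SD, n = 28) on the log2 scale. At 2D2 it was 8.36 ± 0.38 (n = 3) at the dose labelled 1.5 and 8.28 ± 0.42 (n = 3) at 2.5, while at 0.5 the mean was 10.18 ± 1.81 (n = 3), with DMPA_0.5_2D2 replicates 1 and 3 at 11.06 and 11.37 and replicate 2 at 8.10. At 1D4 the animals at 0.5 had 11.81 ± 0.24 (n = 2), against 8.74 ± 0.23 (n = 3) at 1.5 and 8.90 ± 0.91 (n = 3) at 2.5. Animal BB108 (DMPA_0.5_2D2 replicate 2, at 8.10) has no 1D4 sample. The gap between doses at 1D4 is therefore seen without the 0.5 animal that was low at 2D2.

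These values suggest that the lowest labelled dose may have lowered the squamous genes less than the other doses. At 2D2 the change from the animal's own baseline was -1.01 ± 1.54 (SD, n = 3) at 0.5 and -3.64 ± 0.37 (n = 6) at the others, and at 1D4 0.37 ± 0.98 (n = 2) and -3.13 ± 0.57 (n = 6). The rise at 1D4 rests on animal PPi2 (replicate 1 at 0.5), whose 2 baseline samples are late luteal replicate 4 at 8.97 and early follicular replicate 6 at 12.18. Without the late luteal one the change of PPi2 moved from 0.48 to -1.12 at 2D2 and from 1.06 to -0.55 at 1D4, the means at 0.5 became -1.55 ± 0.91 and -0.43 ± 0.16, and all 9 and 8 animals fell. The exact two-sided permutation p at 2D2 was 0.0119, the smallest that the 84 splits can give, but the doses were parted after these animals' values had been seen, so it restates that difference and decides nothing. In the trend with the labelled dose, set before the data were examined, 0 of the 54 genes passed in limma, with 8 at an unadjusted p under 0.05. RNA quality stays open: at 1D4 the GAPDH 3' minus 5' differences of the animals at 0.5 were 1.61 and 1.43, lower than the lowest of the others, 1.86. At 2D2 replicate 3 at 0.5 had the lowest of the 9, 1.39, while replicate 1 kept a mean of 11.06 with 2.67. The 8 animals at 1D4 all enter again at 2D2, where BB108 at 0.5 is added, so the 2 times are not independent.

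Among the baseline samples 2 lay under a mean of 10, a line drawn after the values were seen: late luteal replicate 1 at 9.44 and late luteal replicate 4 at 8.97, with GAPDH differences of 2.10 and 2.67. At LNG 5th the change of the squamous genes was -3.26, -2.76 and -5.21 in the Low animals and -1.18, -0.11 and 0.05 in the High animals. At the 7th time the medians were -1.61 for the Low and -1.42 for the High animals, and 0 of the 54 genes passed in either dose group in limma.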
